A study of Mus musculus with 6 samples.

How the data were processed

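Poly(A)-selected RNA from mouse hippocampus was sequenced in 6 libraries, 3 from the vehicle control group and 3 from the clothianidin (CLO) group, per the labels. Clothianidin is a neonicotinoid insecticide that acts on nicotinic acetylcholine receptors. The labels' protocols state that RNA came from the hippocampus of offspring, that RNA had to pass an integrity minimum, and that the kit kept the strand of the transcripts. The labels do not give the sex, the age, the litter or the sire of the animals, nor a sequencing or library batch. The series description speaks of dosed males, while the protocol names offspring, and the samples were treated here as offspring. The labels also do not say whether the 3 libraries of a group came from separate litters. P-values therefore measure the spread between these libraries, which may share parents or preparation.

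The deposited count table holds whole-number read counts per gene with no normalization, 1 column per library, and 56514 rows. Of these, 1103 rows are loci with no gene annotation, which were left out of library sizes and tests here and were put back as an alternative. The other 55411 rows carry Ensembl gene identifiers. The authors' TPM table (transcript abundance scaled to gene length and library total) gives the gene symbol, the position and the length used for each row. Each deposited TPM value was recomputed from the counts and that length to within 5e-04, the rounding of the table. The submitters' processing notes name cutadapt 2.9, HISAT2 2.2.0, featureCounts 2.6.0 and the genome build GRCm39, with no role or order, and the annotation release and the counting options are not given in the sources used here. Coordinates are those of the deposited table. The reference annotation at hand is for another build, so it was used only for biotype and GC content by gene identifier. It matched 99.8% of the genes tested.

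Some features of the counting can be read from the counts. The mitochondrial gene mt-Co2 and its nuclear copy Gm28661 had counts within 0.721% of each other in every library. Reads that map to several places therefore appear to be kept, either counted at each place or shared between the places, which this pair cannot tell apart. Counts of paralogs, pseudogenes and multigene families are thus uncertain. Of 170 members of the ribosomal, nuclear oxidative phosphorylation and mitochondrially encoded lists, 6 had under 10 counts in all libraries together. These were Uqcrb, Atp5o, Rps10, Ndufa13, mt-Co3 and mt-Nd4, genes that every cell uses. All but Uqcrb overlap a gene on the same strand, so a low count need not mean low expression, with or without such an overlap. Among the genes named in the text, Meg3, Hecw1, Chrm2, Chrna7, Rpl17, Pclo, Impact, Grm4, Grik3, Kmt2c, Kmt2a, Gabra3, Gad2, Reln, Erbb4, Shank1, Dlg1, mt-Atp6, Hsd11b1, Ddx3y and Xist overlap a gene on the same strand, so their levels are uncertain. Of the 1059 symbols on the fixed lists, 1039 were found in the table and 52 of them had under 10 counts in total.

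Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, libraries were scaled by TMM factors, and a robust quasi-likelihood test compared CLO with control without a block, two-sided, with Benjamini-Hochberg adjustment over 16129 genes and a threshold of 0.05. Levels are given as TMM-scaled CPM (read counts relative to the scaled library total), computed here from the deposited counts. A fold change is CLO over control. A gene is said to pass if it does so in this fit of all 6 libraries, unless another setting is named. Lists of genes were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with adjustment over 39 lists, and beside it with the correlation estimated per list and with fry. Of the 40 lists fixed before the data were examined (22 of functions and 18 of cell types), the sex-linked list had fewer than the 5 tested genes required. Principal components and correlations between libraries used log2 CPM with a prior count of 2.

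The genes named follow a rule fixed before the data were examined. It takes up to 12 genes per direction with the largest fold change among those past the threshold, with a mean of at least 1 CPM in the higher group and no overlap between groups. Where fewer than 5 qualify in a direction, those with the smallest p under the same limits on mean and overlap are added up to 5. Model names and pseudogenes are skipped. It also takes up to 4 genes with the smallest p from each list, and always Chrna4, Chrna7, Chrnb2 and the sex-linked genes. Any other gene named was chosen after its values were seen, and which of the rule's candidates serve as examples was also chosen with their values in view.

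The scripts were tested on simulated data. For CLO against control, 200 of 15939 simulated genes were changed by known folds. Of these, 98.5% of genes changed 4-fold, 79.1% of genes changed 2-fold and 19.4% of genes changed 1.5-fold were recovered at the threshold, with 8 false calls among 139. Only well-counted genes were changed, and genes were drawn independently, without trends shared by the genes of a library. These shares therefore need not hold for the real libraries, and a lack of calls there does not show that 2-fold changes are absent.

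Alternatives fixed before the data were examined were RLE, upper quartile and no scaling factors, no filter, and a filter of 1 CPM in 3 libraries. Others were DESeq2 1.42.0, limma-voom with and without sample quality weights, non-robust estimation, the replicate number as a block, each library left out in turn, other thresholds, and limma with a trend on log2(TPM + 1) or log2(TPM + 0.1). Added after seeing the data were fits with each library's trend against gene length, or against length and GC content, removed by an offset (loess span 0.3), a fit of protein-coding genes, a fit with the unannotated loci, and a fit without control libraries 1 and 2.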

Results

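The study asked whether exposure of male C57BL/6N mice to clothianidin (CLO) at 50 mg/kg/day alters messenger RNA levels in the hippocampus and affects the next generation. Hippocampal RNA of 3 CLO and 3 vehicle control samples was compared. The control libraries held 25232305, 26812580 and 26688021 counts and the CLO libraries 19637402, 21189231 and 20783790, so that each CLO library was shallower than each control library. All 6 libraries had 0 counts of Xist, the RNA of the inactive X chromosome, and 101 to 807 counts of each of the Y-linked genes Kdm5d, Eif2s3y, Uty and Ddx3y. Male RNA was thus present in each library. Xist overlaps a gene on the same strand, so its count of 0 sets no upper level.

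No gene passed the adjusted threshold between CLO and control by edgeR with all libraries. The genes with the smallest p that the naming rule takes in each direction were Prkcd, higher in CLO, and Meg3, lower in CLO. Prkcd, which encodes protein kinase C delta, was at 8.69 ± 1.92 CPM in control and 22.7 ± 0.286 in CLO (SD, n = 3), a 2.61-fold difference. Its log2 fold change was 1.38 ± 0.19 (SE), with an adjusted p of 0.127 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the smallest of all genes. Prkcd passed in 5 of 24 other settings, namely by DESeq2 (adjusted p = 2.04e-07), with no filter, with sample quality weights, without control replicate 1 (0.0258) and without control replicate 3 (0.0445). It lies on chromosome 14 from 30317311 to 30348167 (GRCm39). Meg3, a maternally expressed long noncoding RNA of the imprinted Dlk1-Dio3 region on chromosome 12 (109506884 to 109538160), was at 123 ± 68.9 CPM in control and 31.9 ± 9.17 in CLO. Its log2 fold change was -1.94 ± 0.36 (SE), with an adjusted p of 0.167 by the same test in edgeR, and control replicate 1 alone stood at 196 CPM. Meg3 passed in 3 of 23 other settings, by DESeq2, with quality weights and without control replicate 3 (adjusted p = 0.0324), and its log2 fold change was -0.90 without control replicates 1 and 2.

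The other 8 genes that the naming rule takes by p did not pass by edgeR with all libraries either. All 8 passed by DESeq2, with adjusted p from 0.00114 (Ly6c2) to 0.0183 (mt-Tl1), and also with no filter and with quality weights. Like Prkcd and Meg3 they were picked by small p in these same counts. Those settings called 206, 699 and 3473 genes in all, so passing there is not separate evidence. These 8 genes are not the next by p. Among the 61 genes down to the last of them 45 were pseudogenes, 44 of these higher in CLO, and 3 had only model numbers or pseudogene names. Of the 13 others the rule took 10, Prkcd and Meg3 among them, and its other limits left out the rest. Higher in CLO were Lefty1, a secreted inhibitor of Nodal signalling, at 9.67 ± 2.80 CPM in control and 19.4 ± 2.11 in CLO, and Lrrc10b, at 33.1 ± 8.67 and 59.6 ± 3.18 CPM. Tmem52, at 0.707 ± 0.0998 and 2.16 ± 0.451 CPM, and Ly6c2, at 0.326 ± 0.261 and 2.18 ± 0.883 CPM, were near the lower limit of detection. Ly6c2 belongs to a gene family whose members can share reads. Lower in CLO were Hecw1, which encodes a ubiquitin ligase, at 37.3 ± 7.73 CPM in control and 19.4 ± 4.22 in CLO, and Leng8, at 14.6 ± 1.77 and 7.95 ± 1.27 CPM. Akap8l, at 1.67 ± 0.391 and 0.432 ± 0.163 CPM, and the mitochondrial transfer RNA gene mt-Tl1, at 1.53 ± 0.231 and 0.398 ± 0.0995 CPM, were low in both groups, and mt-Tl1 is only 75 bp long. The rule takes only genes without overlap between the libraries of the groups, so for these 8 genes this was fixed in advance. It held for 14.5% of all genes tested, where chance gives 10%.

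**Figure D1:**
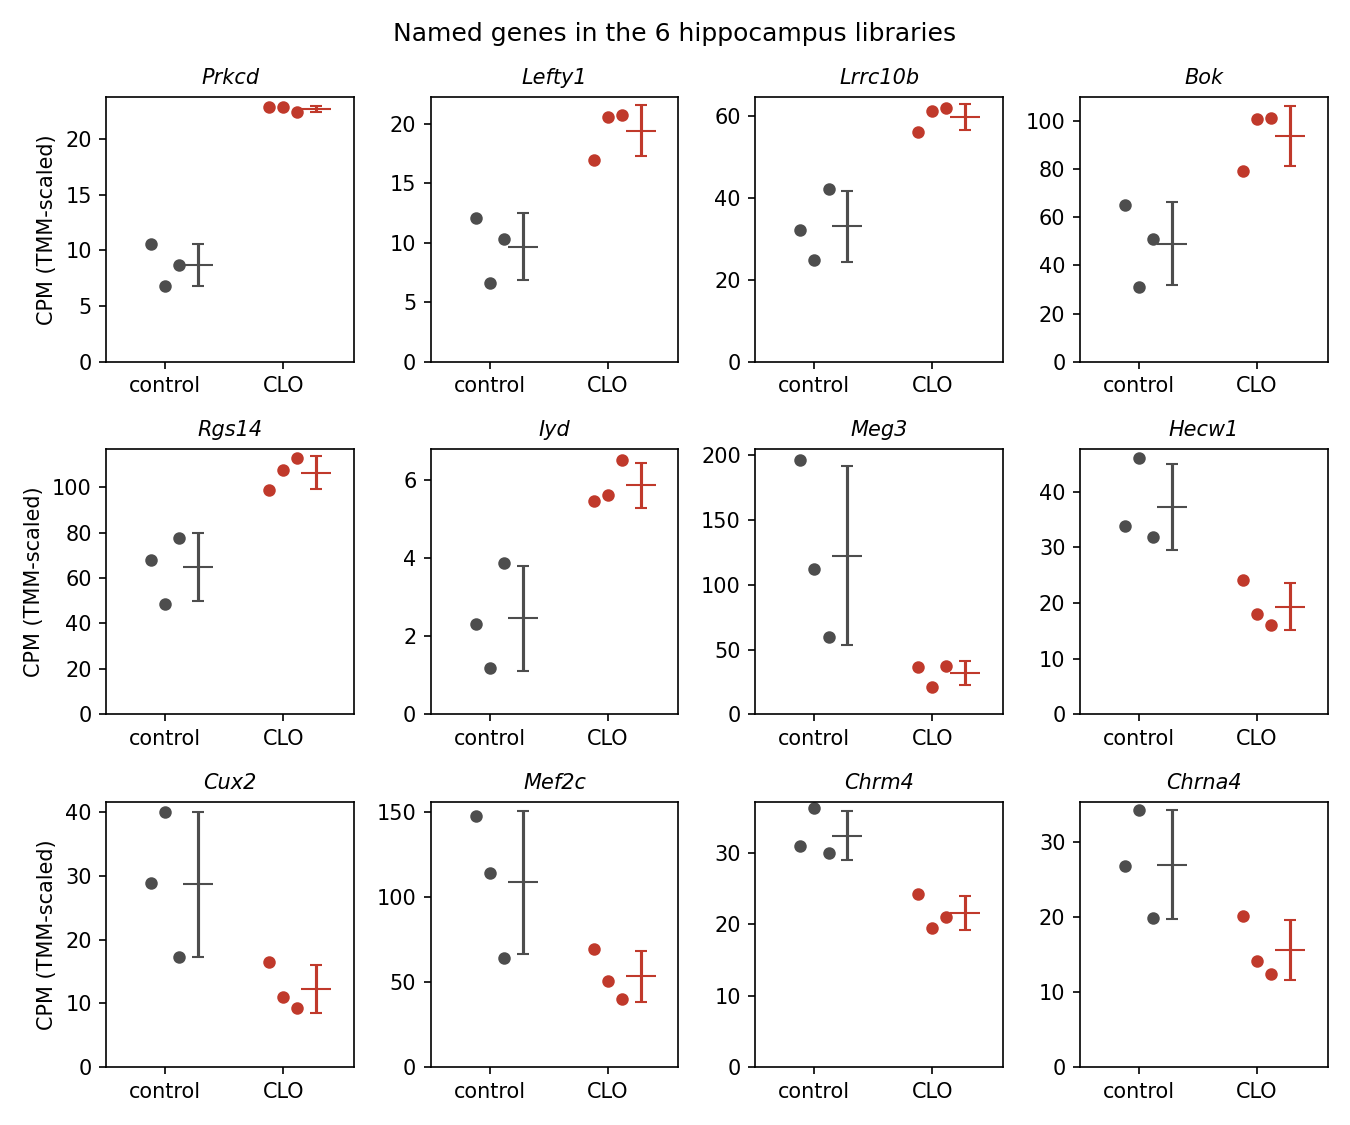
Level of 12 named genes in each hippocampus library, in TMM-scaled CPM on linear axes that start at 0; points are libraries (3 control, 3 CLO), and the dash with its bar is the mean and SD. Prkcd stood at 8.69 CPM in control and 22.7 CPM in CLO on average, and Meg3 varied widely among the controls.

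By edgeR 0 of 16129 genes passed, against 2167 genes at an unadjusted p under 0.05 (996 higher and 1171 lower in CLO), where 806 would be expected with no effect and independent genes. That excess varied with the library left out. The unadjusted count was 3980 without control replicate 1, 3562 without CLO replicate 1 and 2375 without control replicate 3. It was 859 without control replicate 2, and 999 and 950 without CLO replicates 2 and 3, in fits that also have less power. The count of genes past the adjusted threshold was also 0 by limma-voom, 206 by DESeq2 and 3473 by limma-voom with sample quality weights. It was 699 with no filter on low counts. The directions differed too, with 142 higher and 64 lower by DESeq2 and 235 higher and 464 lower with no filter, and 116 of the 142 were pseudogenes, whose counts are uncertain. The number of differing genes depends on the test. Leaving out control replicate 3 gave 20 genes, among them Prm1, Prm2, Tnp2 and Ldhc, which were chosen after their values were seen. These are transcripts of spermatids, and over 9 such genes control replicates 1 and 2 had 356 and 132 counts and each other library 3 or fewer. Leaving out control replicate 1 gave 2 genes.

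Most markers of CA2 and CA3 neurons had higher values in CLO and most markers of the adjoining cortex had lower values, while those of CA1 and of the dentate gyrus went both ways. Of 13 measured markers of CA2 and CA3 pyramidal neurons, 11 had higher and 2 lower values in CLO, with a median log2 fold change of 0.48. Camera called the list (adjusted p = 1.03e-06), but not with an estimated correlation (adjusted p = 0.417). None of the 13 passed over all genes by edgeR with all libraries, although Bok, Rgs14 and Iyd did by DESeq2 (adjusted p = 0.0161, 0.0288 and 0.0301). By edgeR 8 passed, all higher in CLO, when adjusted over the list alone. Among them, Bok, a BCL2-family gene, was at 49.1 ± 17.1 CPM in control and 93.7 ± 12.6 in CLO. Rgs14, a regulator of G-protein signalling typical of CA2, was at 64.8 ± 14.8 and 106 ± 7.23 CPM. Iyd, which encodes iodotyrosine deiodinase, was at 2.46 ± 1.35 and 5.88 ± 0.576 CPM. Markers of CA1 neurons (median log2 fold change -0.05 and mean 0.03 over 11 genes) and of dentate granule cells (median -0.12 and mean -0.02 over 14 genes) were not called, with camera adjusted p-values of 0.462 and 0.978. In both lists the test's direction was up although the median was below 0. Single members were nonetheless higher in CLO, namely Lefty1 and Spink8 of the CA1 list (Spink8 at 17.1 ± 5.94 and 29.6 ± 7.19 CPM) and Lct of the dentate list (25.9 ± 13.3 and 46.1 ± 3.60 CPM). Of these, Lefty1 passed when adjusted over the list alone, and 0 genes of these lists passed over all genes by edgeR with all libraries. Lefty1 passed over all genes by DESeq2 (adjusted p = 0.00595). Lct was at 41.2 CPM in control replicate 3 but at 17.8 and 18.6 CPM in control replicates 1 and 2. Its log2 fold change ran from 0.165 to 1.34 over the other settings, and Lct passed by edgeR without control replicate 3 (adjusted p = 0.0324).

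Of 19 measured markers of the neocortex, 17 had lower values in CLO, with a median log2 fold change of -0.51 (camera adjusted p = 1.03e-06; adjusted p = 0.417 with an estimated correlation). None passed over all genes by edgeR with all libraries, although Cux2, Mef2c and Whrn did by DESeq2 (adjusted p = 0.00571, 0.019 and 0.0217). By edgeR 8 passed, all lower, when adjusted over the list alone. Cux2, a transcription factor of upper cortical layers, was at 28.7 ± 11.4 CPM in control and 12.2 ± 3.80 in CLO, and Mef2c at 109 ± 42.0 and 53.2 ± 14.8 CPM. Whrn was at 20.3 ± 6.21 and 10.5 ± 2.26 CPM, and Scnn1a at 7.13 ± 0.649 and 4.26 ± 0.240 CPM. Markers of the subiculum and retrohippocampal cortex, of which several are also on the neocortex list, were lower in 13 of 14 genes (median -0.58; camera adjusted p = 1.33e-05; adjusted p = 0.417 with an estimated correlation). Among them Fn1, which encodes fibronectin, was at 43.1 ± 15.9 and 25.3 ± 7.08 CPM, and Etv1 at 89.7 ± 3.32 and 66.9 ± 10.2 CPM. When adjusted over the list alone 2 of the 14 passed, both lower, and 0 over all genes by edgeR with all libraries. The mean deviation of the neocortex markers was 0.72 and 0.39 log2 units in control replicates 1 and 2 but -0.14 in control replicate 3 and -0.07 in CLO replicate 1, so the libraries of the groups overlapped. Control replicates 1 and 2 are also the libraries that held the spermatid transcripts. A fit without both, an alternative chosen after seeing the data, has control replicate 3 as its only control, so only medians are given. The median was -0.06 for the neocortex list, 0.33 for the CA2 and CA3 list and -0.36 for the retrohippocampal list. In the same fit it was -0.29 for dentate granule cell markers and 0.19 for endothelial markers. With all libraries, markers of the thalamus and habenula (median -0.33, camera adjusted p = 0.0565) and of the striatum (median -0.17, adjusted p = 0.312) were not called. The thalamus list was called lower without control replicate 3 (median -0.53; adjusted p = 0.000597) and without CLO replicate 1 (0.0283), and it stood at 0.38 and 0.28 in control replicates 1 and 2 and at -0.17 in control replicate 3. Markers of meningeal fibroblasts, not a neural tissue, stood at 0.52 and 0.52 in control replicates 1 and 2 and at -0.58 in control replicate 3. Among the controls this is the order of the neocortex markers. In CLO replicates 1, 2 and 3 the meningeal markers stood at -0.16, 0.29 and -0.59. The neocortex markers were at -0.07, -0.35 and -0.555 there, another order. Prkcd is on the thalamic list, where it moved against the median and passed when adjusted over the list alone.

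**Figure D2:**
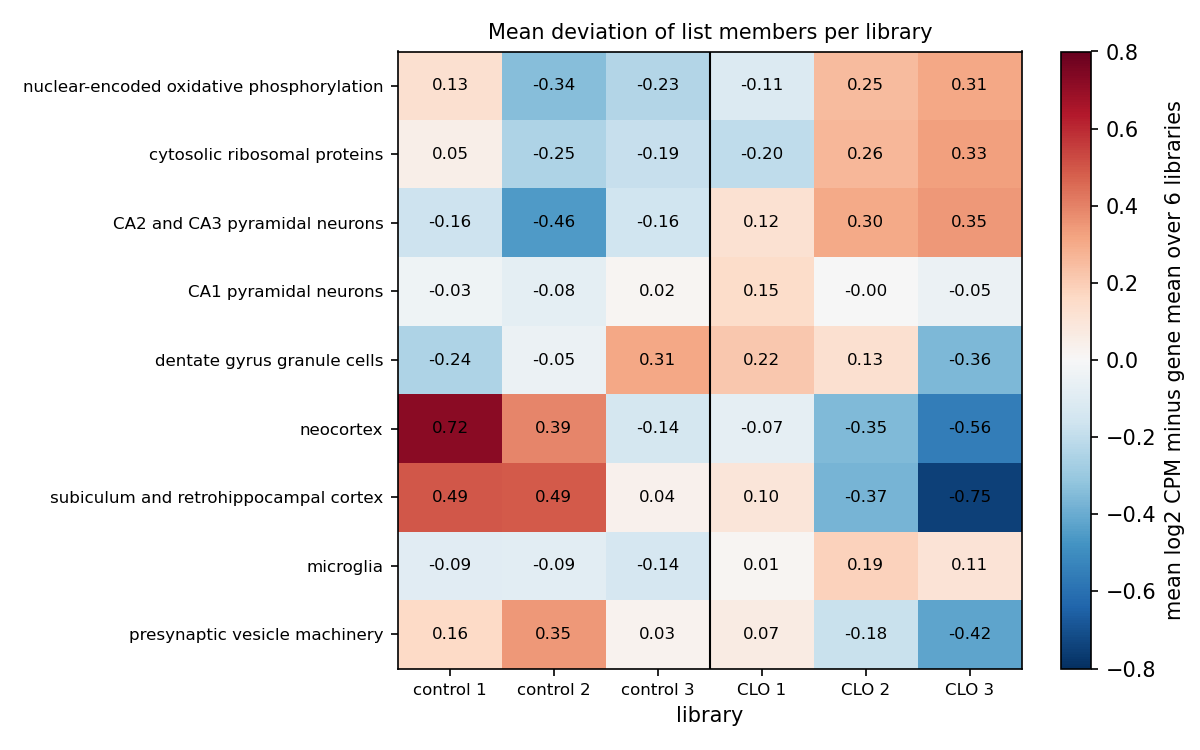
Mean deviation of the members of 9 fixed lists in each library, as log2 CPM minus the gene's mean over the 6 libraries (red above, blue below, number in each cell), with the control libraries left of the line. CA2 and CA3 markers lay between -0.46 and -0.16 in the controls and between 0.12 and 0.35 in CLO, whereas neocortex markers overlapped between groups.

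Most nuclear genes of oxidative phosphorylation and most ribosomal protein genes had slightly higher values in CLO, and none of them passed. Of 73 measured nuclear genes of oxidative phosphorylation, 71 had higher values (median log2 fold change 0.30; camera adjusted p = 6.24e-12; adjusted p = 0.556 with an estimated correlation). Atp5l, a subunit of the ATP synthase, was at 144 ± 24.5 CPM in control and 226 ± 45.6 in CLO, and Sdhd, of succinate dehydrogenase, at 73.5 ± 8.82 and 101 ± 18.6 CPM. Of 78 cytosolic ribosomal protein genes, 77 had higher values (median 0.27; camera adjusted p = 2.91e-10; adjusted p = 0.592 with an estimated correlation). Rpl17 was at 196 ± 7.90 and 259 ± 19.9 CPM, and Rplp0 at 387 ± 21.8 and 525 ± 98.3 CPM. With 1 library left out the medians ran from 0.21 to 0.48 for oxidative phosphorylation and from 0.18 to 0.42 for ribosomal proteins. No gene of either list passed over all genes or when adjusted over the list alone, and the libraries of the groups overlapped for both lists. Ribosomal protein genes have many pseudogenes that can share their reads. The 13 measured genes encoded by the mitochondrial genome, 10 of them lower, were not called (median -0.21, camera adjusted p = 0.3). They were called lower by camera when the length trend was removed (adjusted p = 4.4e-05), without control replicate 1 (median -0.40, 0.000757) and without CLO replicate 3 (0.00081). Without control replicate 3 the median was 0.01. Of these, mt-Nd3 was at 1464 ± 278 CPM in control and 2576 ± 558 in CLO, and mt-Nd5 at 4337 ± 938 and 2710 ± 302 CPM. Both passed when adjusted over the list alone, as did mt-Atp6, which overlaps another gene and was read at only 1.90 ± 0.335 and 0.7997 ± 0.293 CPM. Over all genes 0 passed by edgeR with all libraries, while mt-Nd3 (adjusted p = 0.0161) and mt-Nd5 (0.0337) passed by DESeq2.

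The nuclear lists above lie along a trend with the deposited gene length, whereas the mitochondrially encoded genes, short (median 1103 bp) but mostly lower, go against it as a set. Among them, however, mt-Nd3 (348 bp, higher) and mt-Nd5 (2329 bp, lower) lie along it. The deposited length need not be that of the transcript: for mt-Atp6 it is 1464 bp, although the gene spans 7927 to 8607. Across all 16129 genes, which are not independent replicates, the log2 fold change was correlated with log2 gene length at r = -0.498. The median log2 fold change was 0.27 among the fifth of genes with the shortest gene length (56 to 2010 bp) and -0.25 among the fifth with the longest (7597 bp and more). Among 1393 pseudogenes tested, 527 were higher and 11 lower in CLO at an unadjusted p under 0.05, against 435 higher and 1101 lower of 13720 protein-coding genes. When each library's length trend was removed, an alternative chosen after seeing the data, the calls of the CA2 and CA3, neocortex, retrohippocampal, oxidative phosphorylation and ribosomal lists were kept. The median went from 0.30 to 0.15 for oxidative phosphorylation, from 0.27 to 0.11 for ribosomal proteins and from -0.26 to -0.08 for presynaptic vesicle genes. The calls of the glutamate receptor, chromatin modifier, microglia, circadian and oligodendrocyte precursor lists were lost, and the postsynaptic density list turned to a higher, uncalled value.

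Most genes of 6 synaptic and interneuron lists had lower values in CLO, and none of these lists kept its call with an estimated correlation. Of 36 genes of presynaptic vesicles, 29 had lower values (median log2 fold change -0.26; camera adjusted p = 7.12e-05; adjusted p = 0.496 with an estimated correlation), among them the active zone genes Pclo (113 ± 39.8 and 62.4 ± 15.5 CPM) and Rims2 (47.5 ± 12.1 and 29.8 ± 8.55 CPM). Of 30 glutamate receptor genes and partners, 25 had lower values (median -0.26; camera adjusted p = 0.00035; adjusted p = 0.556 with an estimated correlation). The metabotropic receptor gene Grm4 was at 13.5 ± 4.92 and 6.16 ± 2.80 CPM and the kainate receptor gene Grik3 at 26.4 ± 8.07 and 12.5 ± 6.43 CPM. The median of the list ran from -0.40 without CLO replicate 1 to -0.15 without CLO replicate 3. Cnih2, an auxiliary subunit of AMPA receptors, went the other way, from 596 ± 130 CPM in control to 932 ± 174 in CLO. Of 23 genes of GABA signalling, 20 had lower values (median -0.23; camera adjusted p = 0.00035; adjusted p = 0.513 with an estimated correlation). Gabra3 was at 65.9 ± 9.17 and 44.0 ± 4.43 CPM, Gabrb2 at 141 ± 19.3 and 97.6 ± 13.7 CPM, and Gad2, which makes GABA, at 85.7 ± 12.9 and 59.2 ± 9.17 CPM. Markers of GABAergic interneurons were lower in 14 of 17 genes (median -0.23; camera adjusted p = 0.00948; adjusted p = 0.417 with an estimated correlation). This call was lost without control replicate 1 (median -0.05; adjusted p = 0.175). Reln (44.1 ± 15.7 and 24.1 ± 7.60 CPM), Erbb4 (27.8 ± 8.50 and 15.1 ± 6.00 CPM) and Gad2 passed when adjusted over the list alone. The postsynaptic density list was called at the edge of the threshold, with 22 of 30 genes lower (median -0.20; camera adjusted p = 0.0482; adjusted p = 0.724 with an estimated correlation), Shank1 at 453 ± 111 and 277 ± 74.3 CPM and Dlg1 at 78.4 ± 14.3 and 56.0 ± 6.92 CPM. Its median ran from -0.35 without control replicate 1 to -0.095 without CLO replicate 3. Neuropeptides and their receptors were lower in 26 of 34 genes (median -0.30; camera adjusted p = 0.0142; adjusted p = 0.417 with an estimated correlation), among them the receptors Cckbr (16.3 ± 9.77 and 6.47 ± 1.25 CPM) and Vipr1 (10.1 ± 1.004 and 6.67 ± 1.17 CPM). No gene of these lists passed over all genes by edgeR with all libraries, and apart from the interneuron list none passed when adjusted over the list alone. By DESeq2 over all genes Pclo (adjusted p = 0.0412), Grm4 (0.0356), Grik3 (0.0367) and Cckbr (0.0186) passed. For Pclo, Grm4 and Cckbr the libraries of the groups overlapped. Cckbr was at 26.4 and 15.7 CPM in control replicates 1 and 2 but at 6.84 in control replicate 3, against 5.46 to 7.87 in CLO. Its log2 fold change ran from -1.7 to -0.0771 over the other settings.

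The targets of neonicotinoids, nicotinic receptors, were tested in a list together with other cholinergic genes, and this list was not called. Of 19 measured nicotinic receptor and cholinergic genes, 10 had higher and 9 lower values (median log2 fold change 0.02 and mean -0.09; camera adjusted p = 0.661, direction down). Chrna4, the main brain alpha subunit, was at 26.9 ± 7.20 CPM in control and 15.5 ± 4.0 in CLO, a log2 fold change of -0.79 ± 0.23 (SE), with an adjusted p of 0.244 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. It lies on chromosome 2 from 180660173 to 180685339. Its partner Chrnb2 was at 52.1 ± 1.09 and 49.3 ± 4.35 CPM, a log2 fold change of -0.08 ± 0.14 (SE) that turned to 0.11 when the length trend was removed. Chrna7 was at 6.75 ± 3.46 and 5.05 ± 0.718 CPM, a log2 fold change of -0.42 ± 0.36 (SE). Control replicate 1 stood at 2.77 CPM against 8.41 and 9.07 in control replicates 2 and 3. Over the other settings the log2 fold change of Chrna7 ran from -0.84 to -0.15. The muscarinic receptor genes Chrm4 (32.4 ± 3.42 and 21.6 ± 2.41 CPM) and Chrm2 (6.25 ± 1.31 and 3.70 ± 0.124 CPM) were lower in CLO. Chrna4, Chrm4 and Chrm2 passed when adjusted over the list alone, at 0.0311 each by edgeR, and 0 of the 19 passed over all genes. Many cholinergic genes were barely read, and 14 of the 33 listed were not tested.

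Imprinted genes, a list fixed because the exposure was paternal, were lower in 33 of 44 measured genes (median log2 fold change -0.21; camera adjusted p = 8e-05; adjusted p = 0.417 with an estimated correlation). By edgeR with all libraries Meg3 passed when adjusted over the list alone and 0 genes passed over all genes. Plagl1, a zinc finger gene expressed from the paternal copy, was at 21.8 ± 6.96 and 12.5 ± 3.19 CPM. Impact was at 162 ± 8.18 and 120 ± 9.71 CPM, and Dlk1 at 13.3 ± 3.78 and 7.89 ± 2.08 CPM. Of 43 genes of DNA methylation and histone modification, 35 had lower values (median -0.14; camera adjusted p = 0.00035; adjusted p = 0.531 with an estimated correlation). The methyltransferase genes Kmt2c and Kmt2a were at 27.2 ± 4.39 and 16.0 ± 4.32 CPM and at 37.6 ± 8.78 and 20.2 ± 7.77 CPM, and Tet2 at 4.71 ± 1.41 and 2.18 ± 0.971 CPM. No gene of that list passed over all genes or when adjusted over the list alone by edgeR with all libraries. By DESeq2 over all genes Kmt2c (adjusted p = 0.0455) and Kmt2a (0.0459) passed.

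Among glial lists, microglial markers were higher in 18 of 20 genes (median log2 fold change 0.23; camera adjusted p = 0.00256; adjusted p = 0.496 with an estimated correlation), with the complement gene C1qb at 54.1 ± 5.27 and 70.8 ± 6.08 CPM and Tyrobp at 13.9 ± 2.37 and 18.6 ± 1.93 CPM. Myelin and oligodendrocyte genes were lower in 23 of 24 (median -0.23; camera adjusted p = 0.000721; adjusted p = 0.592 with an estimated correlation), with Myrf at 29.5 ± 5.32 and 19.4 ± 6.09 CPM and Sox10 at 35.5 ± 6.76 and 26.0 ± 3.45 CPM. This call was lost without control replicate 1 (camera adjusted p = 0.0874) and without CLO replicate 2 (median -0.09; adjusted p = 0.169). Oligodendrocyte precursor markers were lower in 8 of 12 (median -0.27; camera adjusted p = 0.0482; adjusted p = 0.556 with an estimated correlation), and Sox6, at 11.7 ± 2.15 and 6.50 ± 1.39 CPM, passed when adjusted over the list alone. The median of that list ran from -0.45 without control replicate 1 to -0.09 without control replicate 2 (camera adjusted p = 0.27), and it was called in 6 of 17 other settings. Astrocyte markers were not called (median -0.03; camera adjusted p = 0.864). Nor were endothelial cells (adjusted p = 0.978), pericytes (0.111), meningeal fibroblasts (0.0795), choroid plexus (0.551), ependymal cells (0.978) and blood cells (0.764). The meningeal list depended on single libraries. It was called lower without control replicate 3 (camera adjusted p = 2.04e-07), without CLO replicate 2 (6.5e-05) and with the length trend removed (0.0288). Its direction was higher without control replicates 1 and 2, where control replicate 3 is the only control. Pericyte markers were called lower without control replicate 3 (0.0343), without CLO replicate 2 (0.0387) and with the length trend removed (0.0288).

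Most genes of the unfolded protein response and heat shock lists had higher values in CLO, and none passed by edgeR with all libraries. Of 26 genes of the unfolded protein response, 18 had higher values (median log2 fold change 0.20; camera adjusted p = 0.00571; adjusted p = 0.531 with an estimated correlation), with Sdf2l1 at 19.9 ± 6.63 and 38.2 ± 11.95 CPM and Hspa5, the chaperone BiP, at 415 ± 43.9 and 597 ± 97.2 CPM. Heat shock and chaperone genes were higher in 21 of 25 (median 0.16; camera adjusted p = 0.0274; adjusted p = 0.513 with an estimated correlation), with Hspe1 at 68.4 ± 11.5 and 91.0 ± 17.2 CPM, whereas Hspa4l was at 99.0 ± 10.9 and 77.0 ± 12.4 CPM. Circadian clock genes were lower in 18 of 22 (median -0.18; camera adjusted p = 0.00893; adjusted p = 0.556 with an estimated correlation), with Nr1d1 at 95.5 ± 7.88 and 70.3 ± 4.41 CPM and Hlf at 119 ± 22.5 and 75.9 ± 22.6 CPM. The median of the clock list ran from -0.30 without control replicate 3 to -0.08 without CLO replicate 3 (camera adjusted p = 0.0663), and its call was also lost without control replicate 1 (0.142). The labels do not give the time of day of sampling. No gene of these lists passed over all genes or when adjusted over the list alone by edgeR with all libraries. Sdf2l1 passed over all genes by DESeq2 (adjusted p = 0.0326).

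Other lists were not called. Activity-regulated genes had 25 of 36 lower values (camera adjusted p = 0.24, and 0.0263 without CLO replicate 1), with the transcription factor gene Npas4 at 5.80 ± 1.49 and 2.63 ± 1.48 CPM and Bdnf at 35.7 ± 3.63 and 47.1 ± 3.61 CPM. Glucocorticoid-responsive genes were split 14 to 10 (adjusted p = 0.628), with Rasd1 at 31.1 ± 7.97 and 54.4 ± 5.59 CPM, which passed when adjusted over the list alone, and Hsd11b1 at 32.1 ± 0.840 and 44.7 ± 5.63 CPM. Thyroid hormone signalling had 15 of 21 lower values (adjusted p = 0.161), with the receptor gene Thrb at 20.3 ± 0.490 and 12.7 ± 4.38 CPM. The camera adjusted p was 0.16 for monoamine receptors, 0.116 for oxidative stress (called higher at 0.0137 without control replicate 1 and at 0.0348 without CLO replicate 1), 0.538 for neurogenesis and 0.978 for inflammation and interferon response, where the median was above 0 and the test's direction down.

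**Figure D3:**
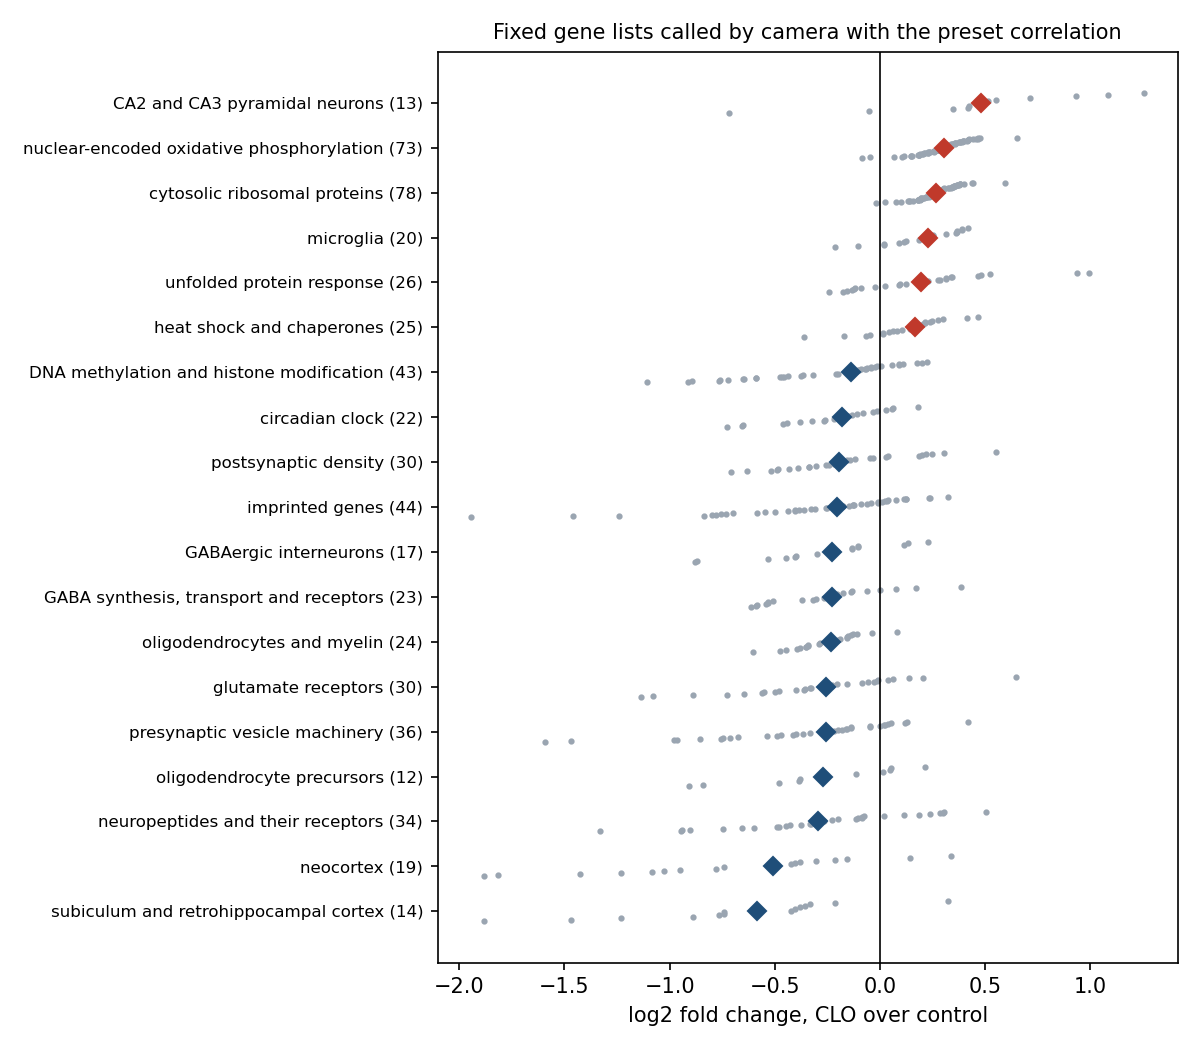
Log2 fold change (CLO over control) of the members of the 19 fixed lists called by camera at the preset correlation; grey points are genes, diamonds are list medians, and the number of tested members stands in parentheses. Medians run from -0.58 for retrohippocampal markers to 0.48 for CA2 and CA3 markers, and most single genes lie close to 0.

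At the preset correlation 19 of 39 lists were called, 6 higher and 13 lower in CLO. Splits of the libraries that mixed CLO and control gave 7 to 17 lists at this setting. With 1 library left out, 11 of the 19 kept their call in every fit and 8 lost it in at least 1, namely interneurons, oligodendrocytes and their precursors, the postsynaptic density, neuropeptides, the circadian clock, the unfolded protein response and heat shock. With the correlation estimated per list 0 were called (smallest adjusted p = 0.417), and 0 by fry (smallest adjusted p = 0.236 for one direction and 0.229 for either). The estimated correlation was 0.809 for oxidative phosphorylation and 0.859 for ribosomal proteins, so the members of these lists moved together within groups as well.

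The first principal component held 46.3% of the variance of the libraries and the second 26.3%. On the first, CLO replicates 2 and 3 stood at 26.8 and 43.4, CLO replicate 1 at -4.80 and the controls between -43.1 and -10.3. The second set control replicate 1, at 41.9, apart from the other libraries, which lay between -28.2 and 3.15. Correlations across genes were 0.976 to 0.989 within groups and 0.963 to 0.989 between them.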

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

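The fits with length or GC trends removed, of protein-coding genes, with the unannotated loci and without control libraries 1 and 2 were chosen after seeing the data. The count of genes by edgeR was 0 under RLE, upper quartile and no scaling, the strict filter, non-robust estimation and the added fits, and 0 by limma-voom and by limma on TPM. It was 699 with no filter, of which 647 had also been tested with the filter, and the median prior degrees of freedom went from 7.92 to infinite. It was 206 by DESeq2 and 3473 with sample quality weights, which ran from 0.323 for control replicate 1 to 4.4 for CLO replicate 2; the cause was not tested. The threshold of unadjusted p under 0.05 and 1.5-fold gave 1208 genes. Leaving out 1 library gave 0 to 20 genes, with 20 without control replicate 3 and 2 without control replicate 1. Same-numbered libraries had deviation correlations of -0.157, -0.0948 and 0.277, and only the third pair correlated best with its own number. With 3 libraries per group this cannot show whether same-numbered samples share a litter or a day. The replicate block gave 0 genes and 19 lists, but other ones: the postsynaptic density (adjusted p = 0.109) and oligodendrocyte precursor lists (0.0785) were lost, and the thalamus and habenula (0.00779) and meningeal fibroblast lists (0.0108) were gained. With no filter 34.7%, without control replicate 2 58.9% and without scaling factors 39.5% of genes at an unadjusted p under 0.05 were higher in CLO against 46% with TMM. The count of 19 called lists became 0 with an estimated correlation and 0 by fry. Both camera runs used the same fit and differed only in the inter-gene correlation, preset at 0.01 or estimated, so the loss came with that choice. The estimates for the called lists ran from -0.000531 for neuropeptides to 0.859 for ribosomal proteins, and all but that of neuropeptides were above 0.01. The cause of the loss by fry was not tested. The count was 17 to 21 with 1 library left out, where 15 to 18 of the 19 kept their call and others were gained. Without control replicates 1 and 2, where control replicate 3 is the only control, the median was 0.00239 for the interneuron list and 0.0462 for the oligodendrocyte list. Of 323 values of called lists under other settings, 247 kept the call and 74 lost it. The postsynaptic density list turned to a median of 0.0383 with the length trend removed and 0.0513 with length and GC removed. Of 1744 values of 73 named genes, 1587 stayed uncalled in the same direction and 146 passed the threshold, mostly with quality weights, no filter or DESeq2. The 11 that turned direction were all uncalled. Chrnb2 was at a log2 fold change of 0.1117 with the length trend removed and 0.109 with length and GC. Eif2s3y was at 0.03586 with quality weights, and from -0.2014 to 0.06031 with 1 library left out, above 0 without control replicate 1. Without control replicates 1 and 2 it was at 0.001285 and Uty at -0.1722. Uty was at -0.05924 with quality weights, -0.00384 on log2(TPM + 1) with and without its filter, and from -0.1813 (without control replicate 1) to 0.2334 with 1 library left out. Ddx3y ran from -0.1652 to 0.01344 with 1 library left out, above 0 without CLO replicate 3. The cause was not tested. The first component held 44.8% with a prior count of 0.5 and 47.2% over the 500 most variable genes. Of 33 cholinergic genes 14 had too few counts to be tested, and whether depth, expression or counting set this was not tested.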

Other observations

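Of 7 long noncoding RNAs other than Meg3, some were lower in CLO and some close to equal, and they were chosen after their values were seen. None passed by edgeR with all libraries. Miat (adjusted p = 0.0023) and Neat1 (0.0372) passed by DESeq2, and Miat passed by edgeR without control replicate 3 (0.0445). Neat1 was at 3.70 ± 2.53 CPM in control and 1.12 ± 0.73 in CLO (SD, n = 3), Miat at 9.51 ± 5.09 and 3.01 ± 0.98 CPM, and Malat1 at 102 ± 75.7 and 61.7 ± 27.1 CPM. Rian, which lies in the same imprinted cluster as Meg3 and is also expressed from the maternal copy, was at 181 ± 14.5 and 180 ± 30.7 CPM, a log2 fold change of -0.01 ± 0.16 (SE). Mirg, of the same cluster, was at 2.03 ± 1.26 and 1.25 ± 0.641 CPM. Snhg14 was at 18.4 ± 1.37 and 18.7 ± 2.37 CPM, and Kcnq1ot1 had a log2 fold change of -0.15 ± 0.30 (SE). Malat1 and Neat1 were highest in control replicate 1 (7.56 and 2.718 log2 CPM), as Meg3 was (7.616). With the length trend removed, the log2 fold change of Meg3 went from -1.94 ± 0.36 to -1.52 ± 0.52 (SE).

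The spermatid pattern was taken up after its values were seen. Meg3 was also examined as a pattern, against length, the rest of its cluster and nuclear RNA, and was put aside for the spermatid pattern because only 3 were to be weighed. The tests of pseudogene copies, of variation of the length trend between libraries, of the regional markers against length and cortex, and of exposure as the reason for spermatid transcripts were chosen after the result was seen, as was the fit without control replicates 1 and 2. The 9 spermatid genes were picked because they showed the pattern, and other germ-cell genes looked at with them, such as Sycp3, Ddx4 and Dazl, did not show it, while Odf1, Spem1, Crisp2 and Tsga8 were highest in control replicate 1, at 17, 16, 8 and 5 counts. The ratios of the single control libraries were also tested only after the pooled one was seen. For the dorsal score the bound against it had been set at 0 or below, and the demand that it be passed by more than its spread was put into the script after the value was seen.

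Over 9 genes transcribed almost only in maturing sperm cells (Prm1, Prm2, Tnp1, Tnp2, Ldhc, Akap4, Smcp, Oaz3 and Gapdhs), control replicate 1 had 356 counts, control replicate 2 had 132 and control replicate 3 had 3, while the CLO libraries had 1, 0 and 0. A further list of 18 spermatid genes, written down before its counts were looked at, was read at 3.77 times the rate in those 2 libraries as in the other 4 (95% exact Poisson interval 3.24 to 4.38, for counting error only), or 2.76 times (2.19 to 3.48) without Dkkl1, which held 361 of the 561 counts there and was left out after its counts were seen. Control replicate 1 alone was at 5.84 times the rate of the other 4 (4.98 to 6.85), or 3.7 times (2.87 to 4.77) without Dkkl1, which is consistent with a trace of testicular RNA, or of reads from testis libraries, while control replicate 2 alone was at 1.81 times (1.46 to 2.24), or 1.88 times (1.38 to 2.54) without Dkkl1, not clear of the bound of 2 set before, so for it this stays open. Exposure cannot by itself set control replicates 1 and 2 apart from control replicate 3, which was also unexposed and had 3 counts over the 9 genes. Whether exposure adds a difference between the groups was not decided. The exact permutation p of the further list was 0.1, the smallest that 3 against 3 allows. Without control replicates 1 and 2, control replicate 3 is the only control, so calls from that fit were not weighed.

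The fall of log2 fold change with gene length is a pattern of the whole transcriptome. After the controls had been thinned at random to the mean depth of the CLO libraries, r was -0.504, against -0.498 before. Such thinning takes reads from all genes of a library at the same rate, so it could hardly have changed the trend. It does not test differences in preparation that may go with the lower depth of the CLO libraries, which stay open. Among protein-coding genes r was -0.423, so the pseudogene rows are not the whole of the trend. Protein-coding genes that share reads with pseudogenes stay in that set, so the shared reads themselves were not tested. A trend that varies from library to library, for example with RNA integrity or fragment selection, cannot be told apart from an effect of exposure, because the slopes overlapped (0.00759 to 0.141 in control, -0.146 to 0.0195 in CLO) with an exact permutation p of 0.2 where 0.1 is the smallest possible. Exposure itself was not tested apart from these.

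The lower cortical and higher CA2 and CA3 markers may reflect the tissue taken. The neocortex median went from -0.51 to -0.06 without control replicates 1 and 2, a fit with control replicate 3 as its only control. The length trend is argued against, since with it removed the larger adjusted p of the neocortex and CA2 and CA3 lists by camera was 2.67e-06, with medians of -0.45 and 0.54, although before this removal neither list was called with an estimated correlation. Less adjoining cortex in the CLO samples would lower cortical markers, and 17 of 19 were lower, but it would raise all hippocampal fields alike; the CA2 and CA3 score less that of CA1 and dentate cells differed by 0.491 log2 units (SD within groups 0.256) with overlapping libraries, so neither part is decided. A more dorsal sampling was tested on dorsal and ventral markers written down before their values were looked at (3 and 5 genes), and the score was -0.135 log2 units in CLO against control (SD within groups 0.333), which is opposite in sign but within its spread; over all markers, including those such as Iyd and Lct already seen to differ, it was 0.476 (SD 0.258, exact p 0.2), so a more dorsal sampling stays open. An effect of paternal exposure on CA2 and CA3 neurons stays open and cannot be told apart from dissection with 3 libraries per group.

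Other splits of the 6 libraries number 10 with the real one, too few for a share under 0.05. The real split called 0 genes and the highest of the others 0, so that all 10 gave as many. For the lists, 1 split, the real one, gave as many as its 19, and the others gave 7 to 17. Camera at the preset correlation thus called lists in every split, also where each side mixed CLO and control libraries. At an unadjusted p under 0.05, the split that sets control replicate 1 with CLO replicates 2 and 3 against the rest gave 4025 genes. The split that sets control replicates 1 and 2 with CLO replicate 1 against the rest gave 2186. Both gave more than the 2167 of the real split.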
